A study of Homo sapiens with 6 samples.

How the data were processed

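Total RNA was sequenced from A375 cells, an established human melanoma line that carries an activating BRAF mutation, after 72 h of treatment. The 6 libraries fall into 3 groups of 2: vehicle (DMSO at 0.01%), 1 µM palbociclib, an inhibitor of the kinases CDK4 and CDK6, and 500 nM GSK3326595, an inhibitor of the arginine methyltransferase PRMT5. The sample titles call the inhibitors PD991 and CTX, which the treatment labels equate with palbociclib and GSK3326595. Per the labels' protocols, cells were grown in RPMI medium, RNA was purified on RNeasy columns, ribosomal RNA was depleted and libraries were made with the TruSeq RNA v2 kit. Transcripts without a poly(A) tail, such as those of replication-dependent histones, can therefore be present in the counts.

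The authors deposited 1 table of raw read counts per gene for each library, indexed by NCBI Gene ID, with no normalization. The submitters' processing notes list CASAVA 1.8.2, cutadapt 1.7, HISAT2, featureCounts 1.6.2, limma and the human genome build hg38. The gene annotation, the strand setting and the handling of reads that align to several places are not given in the sources used here. Genes that overlap an antisense partner and genes with near-identical copies, among them histone, HLA and small RNA genes, are therefore uncertain. Each deposited table holds 28395 gene IDs, and the total count per library ranges from 16589153 to 20842099. Symbols and positions came from the RefSeq gene table of assembly GRCh38, which is the same build as hg38; 27745 IDs matched and 650 did not, and the unmatched IDs held between 0.233% and 0.508% of the counts of a library. They stayed in the library totals and the tests under their IDs. All 13 mitochondrially encoded mRNAs are listed at 0 in each of the 6 libraries, so that list was not tested. These zeros may mean that mitochondrial reads were left out of the counting, which the labels do not state, and are not read as expression values.

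Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16381 genes. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 6 libraries, leaving 3 residual degrees of freedom. The contrasts tested were each inhibitor against DMSO and palbociclib against GSK3326595, by a two-sided quasi-likelihood F test. A gene was called at an adjusted p under 0.05 after Benjamini-Hochberg correction over all genes tested. Errors on log2 fold changes, marked SE, are approximate standard errors derived from the test. Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM, the count scaled to a TMM-adjusted library size of 1000000, as mean ± SD with n = 2. The common dispersion corresponds to a biological coefficient of variation of 0.0839. The names of the 6 deposited tables carry the word repeat, which may mean a repeated sequencing run or a repeated experiment. The labels do not explain it, and they do not say whether the replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical.

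A total of 23 gene lists with 662 members were fixed before the data were examined, along with the design, the alternatives and the rule for naming genes. They cover DNA replication and G1/S, mitosis and G2/M, homologous recombination and Fanconi anaemia repair, replication-dependent histones, p53 targets, cyclins, CDKs and the RB family, arginine methyltransferases and the methylosome, spliceosome Sm proteins and splicing factors, melanocyte differentiation and pigmentation, the dedifferentiated melanoma state, MAPK pathway output, the senescence-associated secretome, interferon-stimulated genes, MHC class I antigen presentation, lysosome and autophagy, sterol synthesis, ATF4 and the unfolded protein response, ribosome biogenesis and MYC targets, extracellular matrix and adhesion, mitochondrially encoded mRNAs, and markers of blood cells, of keratinocytes and other epithelia, and of fibroblasts and endothelium. Lists with at least 5 tested genes, 21 in all, were compared with the other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with the correlation estimated per list, and fry, which tests whether a list moves one way without comparing it with other genes, were the alternatives. In 3 pairs of lists 1 member is shared.

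The genes named are, for each inhibitor against DMSO, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 2 CPM over the 6 libraries, both treated libraries beyond both control libraries and a symbol that is not that of a clone, microRNA or pseudogene. For palbociclib against GSK3326595 the 4 largest of each direction were taken. In each list, the 2 called members with the smallest p in the direction most members took and the 1 with the smallest p in the other direction were added. CDK4, CDK6, CCND1, RB1, PRMT5, WDR77, MDM4, MDM2, CDKN1A, MITF and MKI67 were always included. Some genes that this rule takes are not reported here.

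The test was checked on counts simulated for the 16381 genes, with 100 genes changed at each fold size. The counts were drawn from the DMSO means, the library sizes and the dispersion of each gene in the real data. The means of the inhibitor libraries were not used, also not for palbociclib against GSK3326595. In the simulation of palbociclib against DMSO, 36% of the genes changed by a log2 of 0.5 and 74% of those changed by 1 were recovered, and 8.33% of calls were false. The simulation of GSK3326595 against DMSO recovered 49% and 77%, with 5.97% false calls. For palbociclib against GSK3326595 the recovery was 29% and 66%, with 12% false calls. The share of false calls was above the nominal 5% in these 3 simulations, each a single draw with between 8 and 13 false calls. Far fewer genes were changed in them than were called in the real comparisons (39.5%, 18.8% and 34.8%). The adjusted p depends on that share, so the recovery and false-call shares need not hold for the real data. Changed genes were missed in each simulation, so a gene that was not called is not shown to be unchanged. In further simulations the p53 target list was shifted up by a log2 of 0.5. Camera with the preset correlation and fry called it in each comparison. With an estimated correlation, on 3 residual degrees of freedom, camera gave BH-adjusted p = 0.0152 (palbociclib), 0.0168 (GSK3326595) and 0.0813 (between the inhibitors). It missed the last shift, so a list it did not call is not shown to be unchanged.

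Alternatives were DESeq2 1.42.0 and limma voom as the test, DESeq2 size factors or library totals as the scaling, 2 other filters on low counts, a fit of the compared groups alone, the replicate number as a block, stricter thresholds, and the omission of each library in turn. For the overlap of the inhibitors' responses, chance values were obtained by simulating unchanged groups against the shared DMSO libraries in 100 draws. Transcript isoforms and splicing were not analysed here, since the counts are per gene. GC content and transcript length for a check of bias were taken from the longest transcript of each gene in the reference annotation and fitted by splines with 5 degrees of freedom per term, and intervals on list medians are 95% bootstrap intervals from 10000 draws over genes.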

Results

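RNA-seq counts were obtained from A375 melanoma cells after 72 h with DMSO, 1 µM palbociclib or 500 nM GSK3326595, with 2 libraries per group. Total counts were 17540043 and 19643715 in the DMSO libraries, 19550224 and 20842099 in the palbociclib libraries, and 16589153 and 17932440 in the GSK3326595 libraries. The libraries separated by treatment, with 52.3% of the variance on the first principal component and 25.3% on the second. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 8.33 for DMSO, 5.48 for palbociclib and 10.7 for GSK3326595, so none was merged with another as the same library deposited again. That check does not show that they come from separate cultures.

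The comparison of palbociclib with DMSO asked which transcripts differ after 72 h of CDK4 and CDK6 inhibition. Most transcripts of DNA replication, mitosis and histones fell. MKI67 (Gene ID 4288; GRCh38 chromosome 10, 128096659 to 128126423), a marker of cycling cells, was at 561 ± 16 CPM in DMSO and 157 ± 18.8 CPM with palbociclib (SD, n = 2), a log2 fold change of -1.83 ± 0.101 (SE, edgeR adjusted p = 1.76e-07). All 42 measured mitosis genes fell, 46 of 47 measured replication-dependent histone genes fell, and 27 of 34 lysosome genes and 25 of 34 p53 target genes rose. Among single genes the largest fall was that of the histone gene H4C9, from 114 ± 18.4 to 7.16 ± 1.36 CPM (SD, n = 2), and the largest rise that of LGR6, a receptor for R-spondins. LGR6 (Gene ID 59352; chromosome 1, 202193799 to 202319761) went from 1.34 ± 0.0868 to 22.1 ± 4.47 CPM (SD, n = 2), a log2 fold change of 4.03 ± 0.218 (SE, edgeR adjusted p = 1.71e-07).

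Of the 16381 genes tested, 6470 (39.5%) were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 3159 higher and 3311 lower. At least 2-fold changes made up 1610 of these, 846 higher and 764 lower. Besides LGR6, the largest rises included those of TCN1, a vitamin B12 carrier (log2 fold change 3.65 ± 0.317), PTGS2, which encodes cyclooxygenase-2 (3.43 ± 0.387), ACTBL2 (3.33 ± 0.341) and IFITM10 (2.92 ± 0.303). All of these were below 2 CPM in DMSO. The largest falls after H4C9 were those of H1-1 (-3.85 ± 0.335), FAM111B (-3.16 ± 0.145), H4C1 (-3.14 ± 0.181), H2BC14 (-3.05 ± 0.22) and H1-5 (-2.91 ± 0.178).

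In the DNA replication and G1/S list, 49 of 50 genes fell, 1 rose, and the median log2 fold change was -1.41. CLSPN, which encodes the checkpoint adaptor claspin, fell from 105 ± 4.27 to 29.8 ± 2.21 CPM (SD, n = 2), and PRIM1, the catalytic primase subunit, fell by 2.27 on the log2 scale. The member that rose was CCNE1, which encodes cyclin E1 (log2 fold change 0.52 ± 0.174, edgeR adjusted p = 0.0314). That call was lost without DMSO replicate 1 (adjusted p = 0.0964), DMSO replicate 2 (0.0824) or palbociclib replicate 2 (0.316, with a log2 fold change of 0.30) in the same edgeR test. The mitosis and G2/M genes had a median of -1.39, with ASPM, a spindle pole protein gene, falling from 488 ± 6.75 to 126 ± 3.29 CPM (SD, n = 2) and NUSAP1 by 1.95 on the log2 scale. In homologous recombination and Fanconi anaemia repair, 25 of 28 genes fell, among them BRIP1 (-1.88 ± 0.106) and BARD1 (-2.03 ± 0.12), with a median of -1.18. The histones had a median of -2.27, with H1-3 at -2.87 ± 0.0967 and H4C6 at -2.84 ± 0.109. Histone gene copies are similar in sequence, so the split of reads among them is uncertain. Camera with BH adjustment called all 4 lists lower, at adjusted p = 9.13e-24 for replication, 8.03e-24 for mitosis and for histones, and 5.15e-13 for repair. Each was at adjusted p = 0.336 with an estimated correlation. Adjusted over the list alone, the counts of these 4 lists were the same as over all genes.

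The p53 target list had a median of 0.52, with 25 genes higher, 1 lower and 8 not called, the same counts when adjusted over the list alone. TP53INP1, a p53-induced stress gene, rose from 6.83 ± 0.523 to 24.1 ± 1.23 CPM, and CDKN1A (Gene ID 1026; chromosome 6, 36676463 to 36687332), which encodes the CDK inhibitor p21, rose from 145 ± 2.35 to 379 ± 26.6 CPM (SD, n = 2; log2 fold change 1.39 ± 0.122, edgeR adjusted p = 4.22e-06). The member called lower was POLH, a translesion DNA polymerase gene (-0.26 ± 0.0873, edgeR adjusted p = 0.0343), a call lost without DMSO replicate 1 (adjusted p = 0.1), DMSO replicate 2 (0.19), palbociclib replicate 1 (0.228) or palbociclib replicate 2 (0.0933). It was also lost with DESeq2 (BH-adjusted p = 0.106), with DESeq2 size factors in edgeR (0.0547) and without a filter on low counts (0.0597). Camera called the list higher with BH-adjusted p = 2.69e-07 (adjusted p = 0.336 with an estimated correlation). MDM4, a p53 inhibitor whose pre-mRNA splicing depends on PRMT5, fell (log2 fold change -0.97 ± 0.153, edgeR adjusted p = 4e-04; chromosome 1, 204516406 to 204558120). MDM2, which encodes the main ubiquitin ligase of p53, rose from 274 ± 19.8 to 369 ± 7.15 CPM (SD, n = 2, edgeR adjusted p = 0.00649), a call lost without DMSO replicate 1 (adjusted p = 0.0658) or palbociclib replicate 2 (0.0594).

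Among cyclins, CDKs and the RB family, 2 of 22 genes rose, 9 fell and 11 were not called, also when adjusted over the list alone, with a median of -0.37. RBL1, which encodes the pocket protein p107, fell by 1.43 and E2F8, a repressive E2F, fell by 2.73 on the log2 scale. CCND1 (Gene ID 595; chromosome 11, 69641156 to 69654474), which encodes the CDK4 partner cyclin D1, rose from 489 ± 16.2 to 844 ± 3.56 CPM (SD, n = 2, edgeR adjusted p = 7.98e-05). RB1 fell (-0.50 ± 0.0897, edgeR adjusted p = 0.000961), while CDK4 (-0.17 ± 0.0896; 0.147) and CDK6 (-0.14 ± 0.098; 0.279) were not called by edgeR with BH adjustment. After BH adjustment, camera called the list lower at adjusted p = 0.00902 (adjusted p = 0.336 with an estimated correlation). In the arginine methyltransferase list, 6 of 14 genes fell and 8 were not called, also over the list alone, with a median of -0.24, and camera did not call it (BH-adjusted p = 0.149), except without DMSO replicate 1 (0.0284). Its 6 falls became 0 without DMSO replicate 2 or palbociclib replicate 1 and 1 without palbociclib replicate 2 in edgeR. PRMT5 (Gene ID 10419; chromosome 14, 22920529 to 22929376) was called lower, from 71.2 ± 6.73 to 58.0 ± 2.88 CPM (SD, n = 2, edgeR adjusted p = 0.0358). That call was lost with DESeq2 (BH-adjusted p = 0.0812), with DESeq2 size factors in edgeR (0.0553), and without DMSO replicate 2 (0.324, with a log2 fold change of -0.18), palbociclib replicate 1 (0.211) or palbociclib replicate 2 (0.0865). WDR77, the PRMT5 cofactor, was not called (0.13 ± 0.108, edgeR adjusted p = 0.372). In the spliceosome list, 25 of 39 genes fell, 27 when adjusted over the list alone, and none was called higher by edgeR, with a median of -0.44. TRA2B (-0.88 ± 0.0831) and SRSF10 (-0.82 ± 0.0801), both splicing regulators, were among them, and camera with BH adjustment called the list lower (adjusted p = 3.88e-06; adjusted p = 0.365 with an estimated correlation).

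Lysosome and autophagy genes had a median of 0.60, with 27 higher, none lower by edgeR and 7 not called, the same over the list alone. CTSA, which encodes a lysosomal protease, rose from 89.9 ± 4.46 to 178 ± 9.73 CPM (SD, n = 2), and NEU1, a lysosomal sialidase gene, rose by a log2 of 1.37 ± 0.127. Sterol synthesis genes fell in 13 of 24 cases, 14 adjusted over the list alone, with a median of -0.39. INSIG1, a brake on SREBP processing and itself an SREBP target, went from 80.8 ± 1.96 to 25.9 ± 5.59 CPM (SD, n = 2). In MHC class I antigen presentation 9 of 20 genes rose and 11 were not called, also over the list alone, with a median of 0.20. HLA-B rose from 20.6 ± 0.889 to 49.5 ± 1.40 CPM (SD, n = 2) and HLA-E by a log2 of 0.81 ± 0.0874. HLA genes resemble each other, so their counts are uncertain. Camera with BH adjustment gave adjusted p = 8.12e-10 for lysosome (higher), 0.000499 for sterol synthesis (lower) and 0.00472 for MHC class I (higher). All 3 were at adjusted p = 0.336 with an estimated correlation.

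Extracellular matrix and adhesion genes rose in 13 and fell in 4 of 32 cases (14 and 4 adjusted over the list alone), with a median of 0.16. FN1, which encodes fibronectin, rose from 360.2 ± 9.91 to 939.5 ± 137 CPM (SD, n = 2), ITGA1 rose by a log2 of 1.04 ± 0.0994, and COL1A1 fell by 1.07. In the interferon list 15 of 38 genes rose and 5 fell, also over the list alone, with a median of 0.26; ISG15 (1.02 ± 0.134) and the RNA sensor gene RIGI (1.18 ± 0.154) rose and OAS3 fell by 0.54. Of 17 melanocyte differentiation genes 5 rose, 3 when adjusted over the list alone, and 12 were not called, with a median of 0.37. GPNMB, a melanosomal glycoprotein gene, went from 57.3 ± 7.02 to 174 ± 17.9 CPM (SD, n = 2), whereas MITF, the melanocyte master regulator, was at 59.2 CPM in DMSO and 58.7 CPM with palbociclib (edgeR adjusted p = 0.92). After BH adjustment, camera called these lists higher, at adjusted p = 0.0377 for matrix, 0.0226 for interferon and 0.0341 for melanocyte genes. With an estimated correlation the camera values were adjusted p = 0.336, adjusted p = 0.41 and adjusted p = 0.41. With the replicate number as a block, camera did not call the matrix list (BH-adjusted p = 0.0527). Without DMSO replicate 2 all 3 camera calls were lost, at BH-adjusted p = 0.0584, 0.0568 and 0.0732. The 5 melanocyte rises became 3 without DMSO replicate 1 or palbociclib replicate 2 and 1 without palbociclib replicate 1, and the 5 interferon falls became 3 without DMSO replicate 1, DMSO replicate 2 or palbociclib replicate 2 and 2 without palbociclib replicate 1.

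Camera did not call the remaining lists in this comparison. Fry called the secretome (BH-adjusted p = 0.0113), the dedifferentiated melanoma state (0.0452), and fibroblast and endothelial markers (0.0311). In the senescence-associated secretome 12 of 31 genes rose and 4 fell (13 and 5 adjusted over the list alone; median 0.28; camera BH-adjusted p = 0.0562), with MMP3 (1.96 ± 0.155) and MMP1 (1.64 ± 0.171), both matrix metalloproteinase genes, among those higher and VEGFA lower by a log2 of -0.51. Without DMSO replicate 2 (camera BH-adjusted p = 0.0468) or GSK3326595 replicate 2 (0.0475), with library totals as the scaling (0.0422) or with a filter at 1 CPM (0.0257), that list was called. In the dedifferentiated melanoma state 4 of 24 genes rose and 11 fell (4 and 12 over the list alone; median -0.22; camera BH-adjusted p = 0.213), with the receptor kinase gene AXL (-0.85 ± 0.0962) and TEAD4 (-0.80 ± 0.115) lower and TGFBI higher, from 247 ± 19.7 to 881 ± 27.3 CPM (SD, n = 2). The 11 falls became 7 without DMSO replicate 1 and 5 without palbociclib replicate 2. MAPK output genes rose in 6 and fell in 5 of 25 cases (8 and 6 over the list alone), among them SPRED3 (0.95 ± 0.117) and ETV4 (-0.61 ± 0.0795), with 3 falls without palbociclib replicate 1. Their median was -0.08 and their mean 0.01, and camera placed them lower without a call (BH-adjusted p = 0.932). In ATF4 and the unfolded protein response 3 of 29 rose and 8 fell, also over the list alone (median -0.07; camera BH-adjusted p = 0.34), with the serine synthesis gene PHGDH (-1.23 ± 0.0808) and ASNS (-1.19 ± 0.118) lower and STC2 (1.11 ± 0.136) higher. In ribosome biogenesis 1 of 33 rose and 11 fell, also over the list alone (median -0.23, camera BH-adjusted p = 0.0896). UTP20 (-0.87 ± 0.0837) and the nucleolar methyltransferase gene FBL (-0.71 ± 0.0948) were lower. With the replicate number as a block, camera called the ribosome biogenesis list lower (BH-adjusted p = 0.0329). That list was called lower without DMSO replicate 1 (camera BH-adjusted p = 0.0122) or palbociclib replicate 2 (0.0229), while its 11 falls by edgeR became 3 without DMSO replicate 2, 3 without palbociclib replicate 1 and 4 without palbociclib replicate 2. Of 10 epithelial markers 2 rose and 2 fell, also over the list alone (median 0.08; camera BH-adjusted p = 0.391), with KRT14 and DSP higher. Of 10 fibroblast and endothelial markers 3 rose and 3 fell (4 and 3 over the list alone; median 0.66; camera BH-adjusted p = 0.29), and KDR among them was at 0.245 CPM in DMSO and 3.18 CPM with palbociclib. Of 3 measured blood cell markers LYZ rose, from 4.58 to 13.8 CPM, CSF1R was not called, and CD68 fell by 0.28 on the log2 scale. The CD68 call was lost with DESeq2 (BH-adjusted p = 0.0628) and, in edgeR, without DMSO replicate 1 (0.175), DMSO replicate 2 (0.0545) or palbociclib replicate 2 (0.229).

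With the preset correlation camera called 13 of 21 lists at a BH-adjusted p under 0.05. With the correlation estimated per list it called 0 (2 at unadjusted p under 0.05), and fry called 16. Leaving out palbociclib replicate 1 or replicate 2 lowered the number of genes called to 4195 or 3993.

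The comparison of GSK3326595 with DMSO asked the same of PRMT5 inhibition. Targets of p53 rose in 32 of 34 cases, and cell division genes fell: 42 of 42 mitosis genes, 47 of 50 replication genes and 44 of 47 histone genes. GDF15 (Gene ID 9518; chromosome 19, 18386158 to 18389176), a stress-induced cytokine gene, rose from 15.3 ± 1.31 to 87.4 ± 22.7 CPM (SD, n = 2), a log2 fold change of 2.52 ± 0.168 (SE, edgeR adjusted p = 1.36e-05). MDM2 (Gene ID 4193; chromosome 12, 68808172 to 68850686) rose from 274 ± 19.8 to 665 ± 76.7 CPM and CDKN1A from 145 ± 2.35 to 509 ± 95.2 CPM (SD, n = 2), with edgeR adjusted p = 2.61e-05 and 1.36e-05. RRM2, the small subunit of ribonucleotide reductase, fell from 315 ± 70.8 to 91.7 ± 3.92 CPM (SD, n = 2, edgeR adjusted p = 1.98e-05).

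With edgeR's quasi-likelihood test and BH adjustment, 3081 of the 16381 genes (18.8%) were called, 1406 higher and 1675 lower, and 535 of them changed at least 2-fold, 273 higher and 262 lower. The largest rises were those of the adhesion gene NECTIN4, from 1.21 ± 0.0973 to 8.97 ± 1.07 CPM (SD, n = 2), the lipid phosphatase gene INPP5D (log2 fold change 2.76 ± 0.181), NPR3 (2.56 ± 0.382), GDF15, ELAPOR1 (from 0.779 to 4.46 CPM) and GASK1B (2.47 ± 0.19). Histone genes led the falls, with H1-1 (-2.71 ± 0.303), H2AC19 (-2.58 ± 0.357), H4C9 (-1.81 ± 0.141) and H3C1 (-1.64 ± 0.122), alongside RRM2 (-1.78 ± 0.139) and FBXO43, an inhibitor of the anaphase-promoting complex (-1.66 ± 0.224).

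The p53 target list had a median of 0.97, with none lower by edgeR and 33 higher when adjusted over the list alone; CYFIP2 rose from 16.6 ± 1.61 to 55.6 ± 4.26 CPM (SD, n = 2). Camera with BH adjustment called it higher at adjusted p = 8.54e-23 (adjusted p = 0.436 with an estimated correlation). MDM4 was not called (-0.19 ± 0.151, edgeR adjusted p = 0.409), but without GSK3326595 replicate 1 it was at -0.46 with adjusted p = 0.0211. With the replicate number as a block, edgeR also called MDM4 lower. Counts per gene do not separate the MDM4 isoforms.

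Replication genes had a median of -0.78 (0 higher and 47 lower by edgeR, 48 lower over the list alone), with POLA1, the catalytic subunit of DNA polymerase alpha, at -1.07 ± 0.0947. Mitosis genes also had a median of -0.78, with the same count over the list alone; ASPM fell by 1.25 and the centrosomal kinase gene NEK2 by 1.30 on the log2 scale. MKI67 fell by 0.90 (edgeR adjusted p = 0.000104). Of 28 repair genes 21 fell and 1 rose (22 and 1 over the list alone; median -0.79): FANCI (-1.30 ± 0.0904) and BRCA1 (-0.88 ± 0.0811) were lower and RAD50 higher (0.48 ± 0.0889). Histones had a median of -1.17, with 45 lower over the list alone and H1-3 at -1.30 ± 0.0906. After BH adjustment, camera gave adjusted p = 2.26e-23 for replication, 1.97e-23 for mitosis, 2.17e-11 for repair and 8.7e-23 for histones. With an estimated correlation these were adjusted p = 0.436, adjusted p = 0.445, adjusted p = 0.436 and adjusted p = 0.445.

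Cyclins, CDKs and the RB family had 2 members higher and 9 lower of 22 (2 and 10 over the list alone; median -0.21), with E2F8 (-1.33 ± 0.179) and RBL1 (-0.70 ± 0.0952) lower, and RB1 lower as well (-0.52 ± 0.0902, edgeR adjusted p = 0.00228). CCND1 (0.03 ± 0.1; 0.87), CDK4 (-0.17 ± 0.0898; 0.219) and CDK6 (-0.16 ± 0.0981; 0.29) were not called by edgeR with BH adjustment. Of 31 secretome genes 8 rose and 3 fell (10 and 3 over the list alone; median 0.26), with IGFBP7 (0.81 ± 0.119) among those higher. Of 33 ribosome biogenesis genes 11 rose and 2 fell, also over the list alone (median 0.15), among them NOP2 (0.53 ± 0.0818) and PES1 (0.63 ± 0.0976). Of 20 MHC class I genes 1 rose and 7 fell, also over the list alone (median -0.15), and HLA-B went from 20.6 ± 0.889 to 12.2 ± 0.901 CPM (SD, n = 2, edgeR adjusted p = 0.00092). Camera with BH adjustment gave adjusted p = 0.013 for cyclins (lower; adjusted p = 0.445 with an estimated correlation), 0.0325 for the secretome (higher; adjusted p = 0.445 with an estimated correlation), 0.00305 for ribosome biogenesis (higher; adjusted p = 0.78 with an estimated correlation) and 0.039 for MHC class I (lower; adjusted p = 0.679 with an estimated correlation). Each of these 4 calls rested on single libraries. In the same camera test cyclins were at adjusted p = 0.135 without DMSO replicate 2 and 0.0718 without GSK3326595 replicate 1, and the secretome at 0.106 without DMSO replicate 1 and 0.195 without GSK3326595 replicate 2. Ribosome biogenesis was at camera adjusted p = 0.149 without DMSO replicate 1 and 0.195 without GSK3326595 replicate 2. The edgeR counts moved too, with 5 cyclin falls without DMSO replicate 2, 4 secretome rises without DMSO replicate 1 or GSK3326595 replicate 2, and 5 and 7 ribosome biogenesis rises without these libraries. The 7 MHC class I falls became between 2 and 4 when any of the 6 libraries was left out. MHC class I was at camera adjusted p = 0.139 without DMSO replicate 2, 0.248 without GSK3326595 replicate 1, and 0.0507 without palbociclib replicate 1 or without palbociclib replicate 2.

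PRMT5 and WDR77 transcripts were called higher with the PRMT5 inhibitor. PRMT5 went from 71.2 ± 6.73 to 93.0 ± 9.69 CPM (SD, n = 2; log2 fold change 0.39 ± 0.101, edgeR adjusted p = 0.0204) and WDR77 changed by 0.45 ± 0.108 (edgeR adjusted p = 0.0142). Without DMSO replicate 1 the edgeR adjusted p was 0.201 for PRMT5 and 0.144 for WDR77, and without GSK3326595 replicate 2 it was 0.115 and 0.0889, with WDR77 at 0.29. These 2 were the called members of the 14 arginine methyltransferase genes, also over the list alone (median 0.14; camera BH-adjusted p = 0.418). Of 39 spliceosome genes 3 rose, 2 fell and 34 were not called (3 and 1 over the list alone; median 0.00; camera BH-adjusted p = 0.857). PRPF8, the core spliceosome protein gene, was at 0.42 ± 0.101 (edgeR adjusted p = 0.0131), a call lost without DMSO replicate 1 (0.121) or DMSO replicate 2 (0.0623).

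Camera called none of the remaining lists, each given here with its BH-adjusted p. Melanocyte genes rose in 2 and fell in 2 of 17 cases, also over the list alone (median -0.01; camera adjusted p = 0.948), with MITF (0.49 ± 0.0901, edgeR adjusted p = 0.00324) and GPNMB (0.61 ± 0.105) higher. Dedifferentiation genes rose in 7 and fell in 3 of 24 cases (8 and 3 over the list alone; median 0.03; camera adjusted p = 0.453), with TGFBI (0.78 ± 0.112) and THBS1 (0.97 ± 0.142) higher, and 4 rises without DMSO replicate 1. MAPK output genes rose in 2 and fell in 7 of 25 cases (2 and 8 over the list alone; median -0.15; camera adjusted p = 0.135), with the AP-1 gene FOSL1 lower (-0.61 ± 0.129) and EGR1 higher (1.91 ± 0.238). Without GSK3326595 replicate 2 camera called that list lower (BH-adjusted p = 0.0333), and edgeR called 4 falls without DMSO replicate 1 and 3 without DMSO replicate 2. In the interferon list 2 of 38 rose and 3 fell, also over the list alone, with IFI35 at -0.70 ± 0.105 and TRIM22 higher, from 2.14 to 6.93 CPM; its median was -0.002 and its mean 0.036, and camera placed it higher without a call (BH-adjusted p = 0.833). Lysosome genes rose in 4 and fell in 1 of 34 cases, also over the list alone (median 0.07; camera adjusted p = 0.286), with ATP6V0A1 (0.59 ± 0.0914) and NEU1 (0.68 ± 0.129) higher. Sterol synthesis genes rose in 1 and fell in 6 of 24 cases, also over the list alone (median -0.06; camera adjusted p = 0.232), with INSIG1 at -0.69 ± 0.128 and falls in 3 cases without DMSO replicate 1 and 2 without DMSO replicate 2. ATF4 genes rose in 2 and fell in 3 of 29 cases (3 and 3 over the list alone; median 0.03; camera adjusted p = 0.7), with ATF3 (1.36 ± 0.179) higher and the cystine transporter gene SLC7A11 (-0.81 ± 0.102) lower. Matrix genes rose in 9 and fell in 8 of 32 cases (11 and 11 over the list alone; median -0.04; camera adjusted p = 0.833), with COL1A1 (1.05 ± 0.126) and COL5A1 (0.77 ± 0.113) higher and COL6A3 (-1.14 ± 0.0967) lower. Of 10 epithelial markers edgeR called 0, also over the list alone, with 1 at unadjusted p under 0.05 (median 0.20; camera adjusted p = 0.418). Of 10 fibroblast and endothelial markers 2 rose, also over the list alone (median 0.11; camera adjusted p = 0.453). Of 3 blood cell markers CD68 fell by 0.42 on the log2 scale (edgeR adjusted p = 0.00728), a call lost without DMSO replicate 1 (0.0551), and LYZ and CSF1R were not called.

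Camera called 9 of 21 lists with the preset correlation and BH adjustment, 0 with an estimated correlation (1 at unadjusted p under 0.05), and fry called 5. Without DMSO replicate 1 or DMSO replicate 2 the number of genes called fell to 1738 or 1750.

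Palbociclib was compared with GSK3326595 to test where the responses to the inhibitors differ. Cell division transcripts were lower with palbociclib than with GSK3326595: 40 of 42 mitosis genes, 41 of 47 histone genes and 35 of 50 replication genes were called lower, and MKI67 was at -0.93 ± 0.0992 (log2 fold change ± SE, edgeR adjusted p = 4.63e-05). Targets of p53 were also lower with palbociclib, 23 of 34, with GDF15 at 14.1 ± 1.75 against 87.4 ± 22.7 CPM and MDM2 at 369 ± 7.15 against 665 ± 76.7 CPM (SD, n = 2). Lysosome genes were higher in 23 of 34 cases and MHC class I genes in 9 of 20, with HLA-B at 49.5 ± 1.40 CPM against 12.2 ± 0.901 CPM (SD, n = 2, edgeR adjusted p = 2.92e-06). Cyclin D1 transcripts (CCND1) were higher with palbociclib, at 844 ± 3.56 against 499.6 ± 47.1 CPM (SD, n = 2, edgeR adjusted p = 0.00017).

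**Figure D1:**
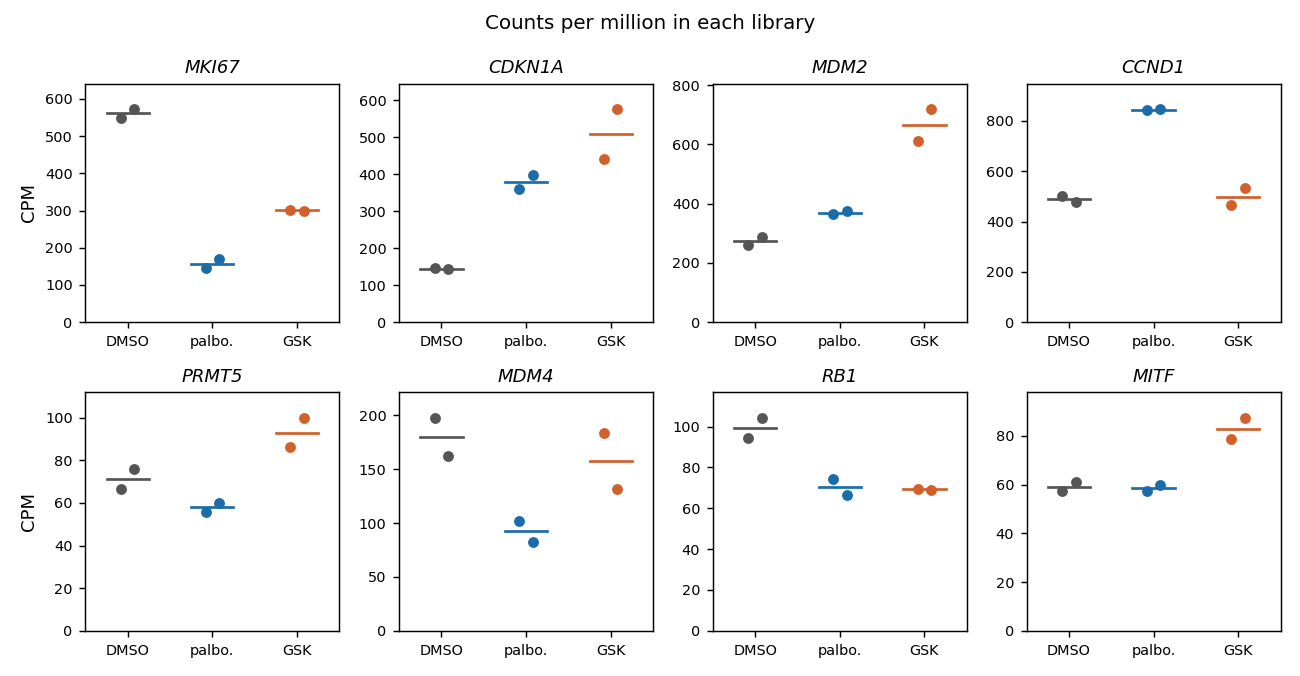
Level of 8 genes in each of the 6 libraries, in CPM on the vertical axis; points are single libraries, bars are group means (n = 2), and the groups are DMSO, palbociclib and GSK3326595. MKI67 falls from a mean of 561 CPM in DMSO to 157 CPM with palbociclib, while MDM2 rises from 274 to 665 CPM with GSK3326595.

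EdgeR with BH adjustment called 5707 of 16381 genes (34.8%), 2718 higher and 2989 lower with palbociclib, of which 1042 differed at least 2-fold, 660 higher and 382 lower. The largest differences upward included those of LGR6 (3.14 ± 0.2), PTGS2 (3.09 ± 0.378) and NEBL (2.39 ± 0.201). Downward they were those of STMN3, a stathmin family gene (-3.68 ± 0.242), GDF15 (-2.63 ± 0.168), INPP5D (-2.39 ± 0.173) and EFEMP1 (-2.35 ± 0.159).

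Medians of the division lists were -0.60 for replication, with 1 gene higher (1 higher and 36 lower over the list alone), -0.67 for mitosis (40 lower over the list alone), -0.47 for repair, with 18 of 28 lower and 1 higher (19 and 1 over the list alone), and -1.05 for histones (44 lower over the list alone). Examples are PRIM1 (-1.69 ± 0.12), the licensing factor gene CDT1 (-1.11 ± 0.092), KIF2C (-0.89 ± 0.0916), BARD1 (-1.06 ± 0.125) and H1-3 (-1.57 ± 0.094); GINS4, a subunit of the replicative helicase, was higher (0.76 ± 0.125). After BH adjustment, camera gave adjusted p = 5.93e-11, 8.89e-14, 1.9e-06 and 1.46e-14 for these 4 lists, each at adjusted p = 0.389 with an estimated correlation. The p53 list had a median of -0.45, with 1 gene higher and the same counts over the list alone, and camera with BH adjustment called it lower at adjusted p = 3.61e-06 (adjusted p = 0.389 with an estimated correlation). Without palbociclib replicate 1 the 23 lower became 14. DDB2, a DNA damage recognition gene, was lower with palbociclib (-0.92 ± 0.0905), and TP53INP1 was the member called higher (0.47 ± 0.118), a call lost without palbociclib replicate 1 (edgeR adjusted p = 0.0969). CDKN1A was called lower with palbociclib (-0.42 ± 0.118, edgeR adjusted p = 0.0154), a call lost without palbociclib replicate 1 (0.139) or GSK3326595 replicate 2 (0.13, with -0.22). MDM4 was lower with palbociclib (-0.77 ± 0.153, edgeR adjusted p = 0.00225), and at -0.49 without GSK3326595 replicate 1. RB1, CDK4 and CDK6 were not called, at edgeR adjusted p = 0.898, 0.971 and 0.903.

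Spliceosome genes were lower with palbociclib in 26 of 39 cases and higher in none by edgeR (28 lower over the list alone; median -0.51), among them SRSF4 (-0.77 ± 0.0907) and TRA2B (-0.68 ± 0.0832). Ribosome biogenesis genes were lower in 19 of 33 cases and higher in none by edgeR (21 lower over the list alone; median -0.36), with FBL at -0.95 ± 0.095. Arginine methyltransferase genes were lower in 6 of 14 cases, also over the list alone (median -0.19), with PRMT5 at -0.68 ± 0.101 (edgeR adjusted p = 0.000364) and its adaptor RIOK1 at -0.65 ± 0.113. WDR77 was at -0.32 ± 0.108 (edgeR adjusted p = 0.0374), a call lost with DESeq2 (0.0629), with DESeq2 size factors in edgeR (0.0541), and without palbociclib replicate 1 (0.196), palbociclib replicate 2 (0.104) or GSK3326595 replicate 2 (0.272, with -0.17). Sterol synthesis genes were lower in 13 and higher in 1 of 24 cases (14 and 1 over the list alone; median -0.39), with INSIG1 at -0.96 ± 0.133 and the sterol regulator gene SREBF2 at -0.68 ± 0.101. Camera with BH adjustment called these lists lower at adjusted p = 1.56e-07 for spliceosome (adjusted p = 0.389 with an estimated correlation), 1.75e-05 for ribosome biogenesis (adjusted p = 0.484 with an estimated correlation), 0.0318 for methyltransferases (adjusted p = 0.587 with an estimated correlation) and 0.00178 for sterol synthesis (adjusted p = 0.389 with an estimated correlation). Without palbociclib replicate 1 edgeR called 17 spliceosome, 11 ribosome biogenesis and 3 methyltransferase genes lower. Without palbociclib replicate 2 it called 12 ribosome biogenesis and 6 sterol synthesis genes lower, and without GSK3326595 replicate 2 11 ribosome biogenesis and 3 methyltransferase genes. The methyltransferase call was lost without palbociclib replicate 1 (camera adjusted p = 0.094) or GSK3326595 replicate 2 (0.172).

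Lysosome genes had a median of 0.53, with 1 gene lower (24 higher and 1 lower over the list alone), and MHC class I genes a median of 0.24 (9 higher and 1 lower over the list alone); CTSA (0.95 ± 0.0833) and HLA-E (1.09 ± 0.0887) were higher with palbociclib. Matrix genes were higher in 15 and lower in 6 of 32 cases, also over the list alone (median 0.23), with COL6A3 (2.02 ± 0.096) and ITGA3 (1.20 ± 0.104) higher and COL1A1 (-2.12 ± 0.135) lower. Melanocyte genes were higher in 6 and lower in 1 of 17 cases, also over the list alone (median 0.52), with GPNMB (0.99 ± 0.103) and the receptor kinase gene ERBB3 (0.76 ± 0.0884) higher and MITF lower (-0.50 ± 0.0898). Interferon genes were higher in 14 and lower in 2 of 38 cases, also over the list alone (median 0.18), with IFI35 (1.20 ± 0.104) and ISG20 (1.04 ± 0.097) higher and HERC5 (-1.33 ± 0.242) lower. After BH adjustment, camera called these lists higher, at adjusted p = 2.02e-08 for lysosome, 9.43e-05 for MHC class I, 0.00314 for matrix and 0.0126 for melanocyte genes, all at adjusted p = 0.389 with an estimated correlation, and 0.0372 for interferon genes (adjusted p = 0.484 with an estimated correlation). The melanocyte call was lost without GSK3326595 replicate 2 (camera adjusted p = 0.0505) and the interferon call without palbociclib replicate 1 (0.0644) or GSK3326595 replicate 1 (0.138), and its 14 genes higher became 9 without palbociclib replicate 2. The 6 matrix genes lower became 2 without palbociclib replicate 1 or palbociclib replicate 2 and 3 without GSK3326595 replicate 2.

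Camera did not call the other 7 tested lists, each given here with its BH-adjusted p. Cyclins, CDKs and the RB family were higher in 2 and lower in 6 of 22 cases (the same over the list alone; median -0.13; camera adjusted p = 0.0981), with CDK2 (-0.76 ± 0.0831) and RBL1 (-0.74 ± 0.0989) lower. Dedifferentiation genes were higher in 3 and lower in 12 of 24 cases, also over the list alone (median -0.26; camera adjusted p = 0.0689), with NRG1 (-0.76 ± 0.1) and TEAD4 (-0.84 ± 0.115) lower and TGFBI (1.06 ± 0.111) higher. MAPK output genes were higher in 8 and lower in 4 of 25 cases (10 and 4 over the list alone; median 0.13; camera adjusted p = 0.0725), with SPRED3 (0.90 ± 0.117) higher and EGR1 (-2.28 ± 0.244) lower. Secretome genes were higher in 11 and lower in 6 of 31 cases (11 and 7 over the list alone; median 0.02; camera adjusted p = 0.581), with IGFBP3 (1.43 ± 0.116) and MMP1 (1.25 ± 0.168) higher and PLAUR (-0.50 ± 0.0885) lower. ATF4 genes were higher in 3 and lower in 7 of 29 cases (3 and 8 over the list alone; median -0.21; camera adjusted p = 0.0725), with PHGDH (-0.85 ± 0.0807) and ASNS (-1.02 ± 0.118) lower and SLC7A11 (0.86 ± 0.102) higher. Epithelial markers were higher in 2 and lower in 2 of 10 cases, also over the list alone (median 0.08; camera adjusted p = 0.549), with KRT14 higher (1.47 ± 0.231). Fibroblast and endothelial markers were higher in 2 and lower in 1 of 10 cases, also over the list alone (median 0.08; camera adjusted p = 0.697). Of 3 blood cell markers LYZ was higher (1.49 ± 0.225). Camera called dedifferentiation (0.0268) and ATF4 genes (0.00564) without GSK3326595 replicate 1, and MAPK genes without palbociclib replicate 1 (0.0435) or GSK3326595 replicate 2 (0.0399), all BH-adjusted p. In edgeR 7 dedifferentiation genes were lower and 5 MAPK genes higher without palbociclib replicate 2, and 12 ATF4 genes lower without GSK3326595 replicate 1.

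Camera called 14 of 21 lists with the preset correlation and BH adjustment, 0 with an estimated correlation (0 at unadjusted p under 0.05), and fry called 13. Without palbociclib replicate 1 or palbociclib replicate 2 the number of genes called was 3299 or 3392.

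**Figure D2:**
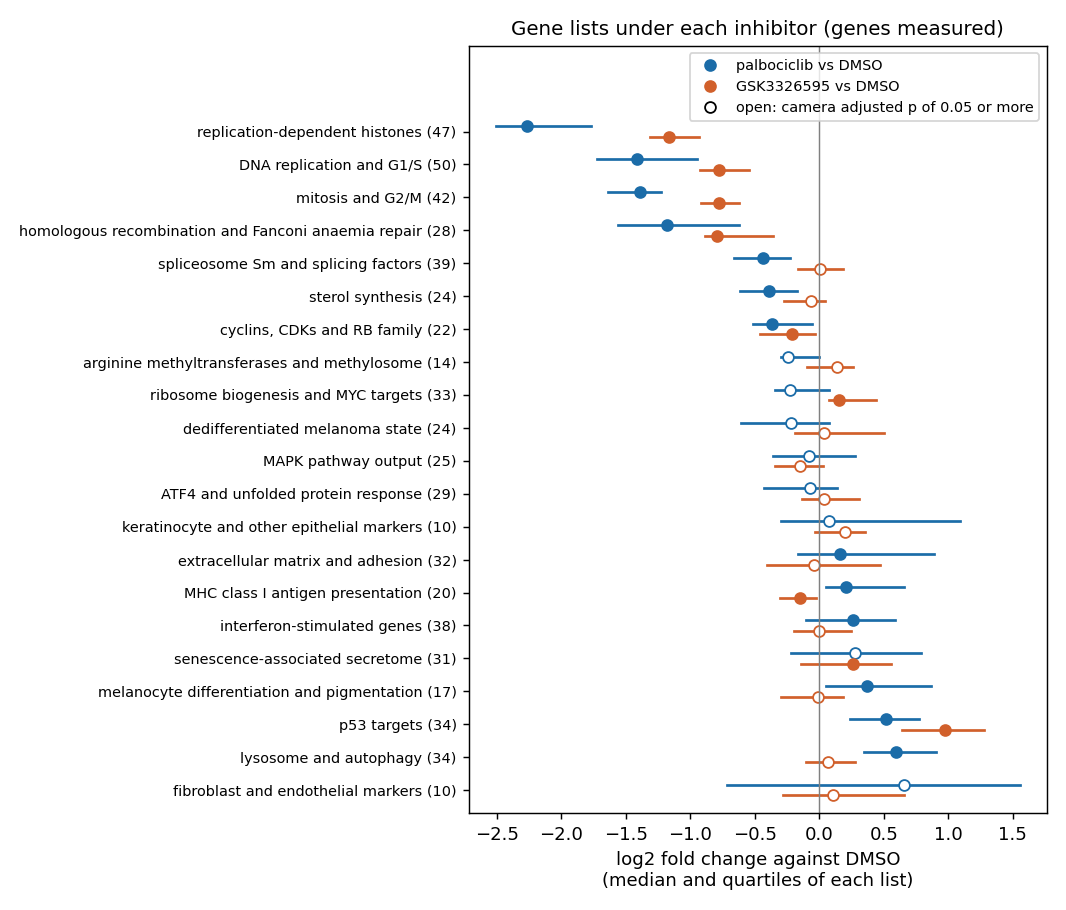
Median log2 fold change against DMSO of 21 gene lists, with the quartiles of their genes as lines, for palbociclib and GSK3326595; filled points mark lists that camera called with the preset correlation of 0.01 at a BH-adjusted p under 0.05. With an estimated correlation camera called 0 lists (2 with palbociclib and 1 with GSK3326595 at unadjusted p under 0.05), where fry called 16 and 5. Histones lie at a median of -2.27 with palbociclib and -1.17 with GSK3326595, and p53 targets at 0.52 and 0.97.

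The overlap of the responses was counted over genes called against DMSO by edgeR with BH adjustment. Both inhibitors changed 1910 genes, of which 1729 (90.5%) went the same way, 694 higher and 1035 lower, and 181 went opposite ways. CDKN1A, TP53INP1, TGFBI, NEU1 and GPNMB were among the genes higher with both inhibitors, and MKI67, ASPM, H1-3, RBL1 and INSIG1 among those lower with both. Among the 181, 116 were higher with palbociclib and lower with GSK3326595, HLA-B and COL6A3 among them, and 65 the reverse, COL1A1 and STMN3 among them. COL1A1 was at 13.3 ± 0.989 CPM in DMSO, 6.31 ± 0.493 CPM with palbociclib and 27.4 ± 1.54 CPM with GSK3326595 (SD, n = 2). Independent lists of these sizes would share 271 higher, 339 lower and 607 opposite genes. The number going the same way was 1120 without DMSO replicate 1, 968 without DMSO replicate 2 and 1099 without palbociclib replicate 2.

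Both comparisons use the same DMSO libraries, so their fold changes share chance values. In 100 simulated draws with no effect, the median number of genes called the same way was 0 and the highest 3, and for opposite ways 0 and 1. With no effect almost no gene is called, so these values do not measure how many shared calls the common controls add where effects exist. Across the 16381 genes, which are not independent replicates, the log2 fold changes of the inhibitors had a correlation of 0.526 and a covariance of 0.177, against simulated medians of 0.498 and 0.0371. The correlation was no higher than the highest simulated draw, also 0.526. The simulated correlation comes from noise alone, at a covariance well below the observed one. It therefore does not measure how much of the observed correlation the shared controls explain. With a separate DMSO library for each inhibitor, the correlation was 0.462, 0.35, 0.253 and 0.315 over the 4 assignments of single libraries. That removes a library used in both comparisons, but not a deviation that both DMSO libraries may share. The covariance lay 0.14 above its simulated median, whose highest draw was 0.0418. With 2 control libraries the controls could not be split into groups of 2, so part of the counts, and of their excess over independent lists, may come from the shared controls.

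**Figure D3:**
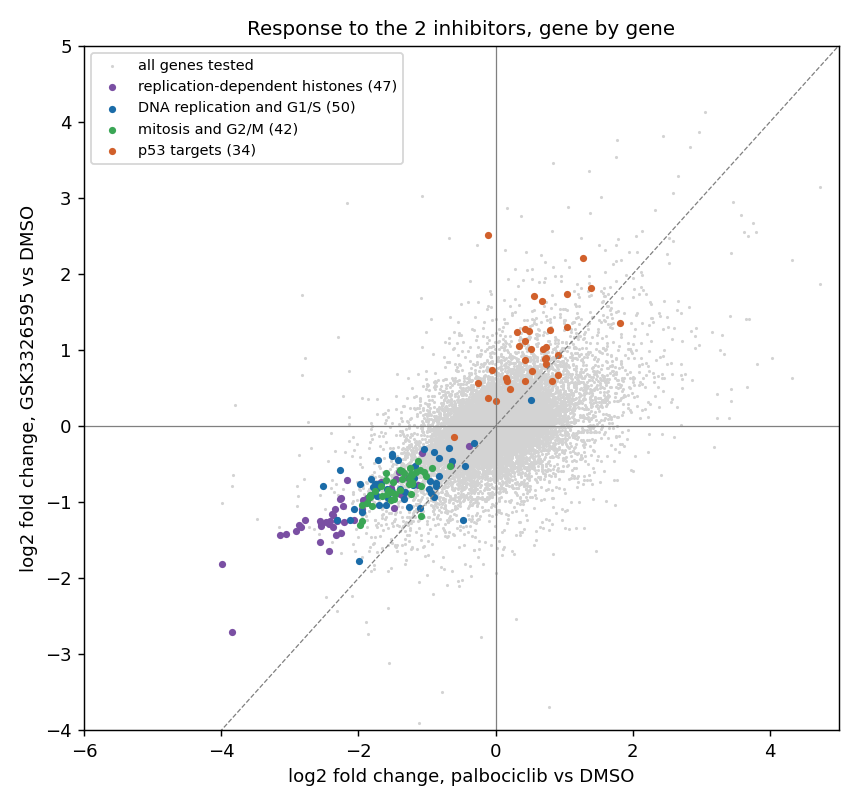
Log2 fold change against DMSO of each tested gene with palbociclib (horizontal axis) and GSK3326595 (vertical axis); points are genes, coloured for histones, DNA replication, mitosis and p53 targets, the dashed line marks equal changes, and 4 genes lie outside the plotted range. Histones and division genes lie lower with both inhibitors, with replication medians of -1.41 and -0.78, and p53 targets higher.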

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

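All alternatives were fixed before the data were examined. The groups and genes of the other observations, however, were chosen after their values were seen. They were then run under the 15 alternative fits, but not under the stricter thresholds. No called gene or list named in the text changed sign under an alternative, and none turned to a call in the other direction. Of the 6470 genes called for palbociclib against DMSO, 1 changed sign without DMSO replicate 1, where it was not called. A stricter adjusted p under 0.01 left 4149 genes for palbociclib against DMSO, 1301 for GSK3326595 against DMSO and 3412 between the inhibitors, with 768 changed the same way by both. A log2 fold change of at least 1 left 1610, 535 and 1042, with 279 the same way. DESeq2 called 5300, 2465 and 4582 genes, limma voom 6516, 2978 and 5688, and library totals as the scaling 6221, 2809 and 5410. With an estimated correlation camera called 0 lists in each comparison, where fry called 16, 5 and 13. That version of camera also missed a simulated shift of the p53 list between the inhibitors (BH-adjusted p = 0.0813). Its lack of calls therefore does not show that a list is unchanged. The 16 lists for palbociclib held all those called with the preset correlation. They added the secretome, dedifferentiation, and fibroblast and endothelial markers. Of the lists called with the preset correlation, the 5 for GSK3326595 left out cyclins, the secretome, MHC class I and ribosome biogenesis. The 13 between the inhibitors left out methyltransferases (fry BH-adjusted p = 0.136), melanocyte genes (0.0552) and ribosome biogenesis (0.0547). They added cyclins (0.0197) and dedifferentiation (0.0213). The labels name no shared day or batch for the 2 replicate numbers, so the main fit did not pair the libraries. Deviations of same-numbered libraries had correlations of 0.179 (DMSO and palbociclib), 0.341 (DMSO and GSK3326595) and 0.14 (palbociclib and GSK3326595). The third principal component, with 12% of the variance, separated replicate 1 (13, 4.82 and 25.3 for DMSO, palbociclib and GSK3326595) from replicate 2 (-18.5, -7.32 and -17.2). An effect shared by libraries of the same replicate number is therefore possible. With that number as a replicate block, the counts were 8716, 5769 and 7913 genes, with 3296 changed the same way by both, and with the block and library totals 8435, 5495 and 7666. In the camera test with the block, extracellular matrix (palbociclib against DMSO; adjusted p = 0.0527) and interferon genes (between the inhibitors; adjusted p = 0.0521) were not called, while ribosome biogenesis (palbociclib against DMSO; adjusted p = 0.0329) and dedifferentiation (between the inhibitors; adjusted p = 0.0436) were. Leaving out 1 library at a time gave between 3993 and 7189 genes for palbociclib, between 1738 and 3206 for GSK3326595, between 3299 and 5519 between the inhibitors, and between 968 and 1825 for both the same way. The lists called ranged from 11 to 15, from 7 to 8 and from 13 to 15. Counts of fewer than 6 genes in a list moved by over 1.5 times in many of these fits. In these fits an arm has 1 library, which is assumed to vary like the other groups. Apart from the genes always included, named genes were picked for the largest changes or the smallest p. Their shares given next are therefore no measure of how stable all calls are. DESeq2, for example, kept 81.3% (palbociclib), 78.4% (GSK3326595) and 79.7% (between the inhibitors) of all calls. The omissions counted also include libraries outside a comparison. Of the named genes' calls over other tests, scalings, filters and samples, 1524 of 1540 were on the same side of the threshold and 16 were lost. Over the omission of single libraries 1252 of 1326 were on the same side, 73 were lost and 1 was gained, and under the block 434 of 442 were and 8 were gained. With the block alone the gains were CDK4 (edgeR adjusted p = 0.0272 for palbociclib, 0.0448 for GSK3326595) and MDM4 (GSK3326595; 0.0149), and with library totals as well also CDK6 (palbociclib and GSK3326595). Among genes chosen after their values were seen, the block alone also gained CIITA (edgeR adjusted p = 0.0322), CD74 (0.000512) and NUP210 (0.00106) for GSK3326595. Between the inhibitors it gained MIR3648-1 (edgeR adjusted p = 2.22e-05). The block also raised the nucleoporin falls with GSK3326595 from 6 to 12, and to 14 with library totals. At this depth and with 2 libraries per group, simulations recovered a log2 change of 0.5 in 36% (palbociclib), 49% (GSK3326595) and 29% (between the inhibitors) of changed genes. They changed far fewer genes than were called here, so these shares need not hold for the real data. Genes that were not called are still not shown to be unchanged.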

Other observations

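The gene groups and single genes described here were chosen after their values were seen, as were the tests of blood-lineage cells and of reads shared between HLA genes. The omission of single libraries and the use of separate DMSO libraries were planned, but the bounds they are held to here were chosen after the values were seen. MHC class II genes, which present peptides to helper T cells, were higher with palbociclib. Of 12 measured members, 11 rose against DMSO (11 when adjusted over the group alone), with a median log2 fold change of 2.46. The members above that median, HLA-DQB1, HLA-DQA2, HLA-DOA, HLA-DRB5, HLA-DMB and HLA-DRB1, were at no more than 1.24 CPM in DMSO. HLA-DQB1, HLA-DQA2 and HLA-DOA passed the low-count filter only through the palbociclib libraries, so their rise is tied to the filter. CIITA, CD74, HLA-DRA, HLA-DPA1 and HLA-DMA, at 6.62 CPM or more in DMSO, rose by 1.33 to 2.43 on the log2 scale. HLA-DRA went from 15.3 ± 2.49 CPM in DMSO to 82.2 ± 18.3 CPM with palbociclib and 23.8 ± 4.11 CPM with GSK3326595 (SD, n = 2; edgeR adjusted p = 8.65e-07 for palbociclib against DMSO). CD74, the invariant chain, rose with palbociclib from 81.3 ± 6.55 to 276 ± 54.6 CPM and CIITA, the class II transactivator, from 13.2 ± 1.21 to 38.3 ± 4.99 CPM (SD, n = 2). HLA-DPB1 was not called (0.26 ± 0.131; edgeR adjusted p = 0.13). With GSK3326595 3 of the 12 rose, which became 0 without DMSO replicate 1 or without GSK3326595 replicate 2 and 1 without DMSO replicate 2, with at most 5 over the 15 alternatives; edgeR called 11 of 12 higher with palbociclib than with GSK3326595, with a median of 1.52. Matrix metalloproteinase genes rose in 11 of 16 cases with palbociclib, with a median of 0.86; without palbociclib replicate 2 the number was 7. With GSK3326595 edgeR called 3 of the 16 higher (MMP2, MMP3 and MMP15), 1 lower (MMP16, -0.45 ± 0.0937, edgeR adjusted p = 0.00621) and 12 not, with a median of 0.312; the MMP2 call was lost without DMSO replicate 2 (adjusted p = 0.0572). MMP2 was at 294 ± 16.1, 610.4 ± 24.8 and 420.1 ± 53 CPM in DMSO, palbociclib and GSK3326595, and MMP15 at 5.71 ± 0.0262, 20.2 ± 1.67 and 12.9 ± 0.613 CPM (SD, n = 2). After the trend with GC content and gene length was removed, the metalloproteinase median with palbociclib was 0.659 (interval 0.387 to 1.635). Among the genes that rose, MMP8, MMP10 and MMP28 were under 1 CPM in DMSO. MMP8 would not have passed the low-count filter without the palbociclib libraries.

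Nucleoporin genes fell in 17 of 22 cases with palbociclib, with a median log2 fold change of -0.63; NUP210 fell by 1.30 and NUP85 by 0.92. NUP210 alone among these fell at least 2-fold. With GSK3326595 6 of 22 fell by edgeR, with a median of -0.204, and of -0.148 without DMSO replicate 2. In a fit of the compared groups alone 3 fell. Over the 15 alternative fits, which leave out the stricter thresholds, the number was between 3 and 14. Of the 6, NUP107 (edgeR adjusted p = 0.00247) and NUP85 (0.00779) were under 0.01, and all were under 2-fold. Among genes that moved opposite ways, MXRA8 was at 39.0 ± 6.36, 78.2 ± 5.93 and 15.4 ± 3.14 CPM in DMSO, palbociclib and GSK3326595 (SD, n = 2). CD274, which encodes PD-L1, was at 6.40 ± 0.45, 3.81 ± 0.639 and 12.03 ± 2.93 CPM in the same groups. Its palbociclib call (edgeR adjusted p = 0.0188) was lost without DMSO replicate 2 (0.0946) or palbociclib replicate 2 (0.15), and its GSK3326595 call (0.00965) without DMSO replicate 1 (0.0586). MIR3648-1, which lies within the ribosomal RNA precursor, had 407.2 and 637.1 CPM in the DMSO libraries, 1039 and 1282 CPM in the palbociclib libraries and 1230 and 1962 CPM in the GSK3326595 libraries. MIR6724-4, of the same precursor, had a fitted log2 fold change of 9.25 with GSK3326595 (edgeR adjusted p = 0.00949) that rested on replicate 2, which held 270.7 CPM while every other library held at most 0.6245 CPM. Without that library its edgeR adjusted p was 0.218.

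Targets of p53 were lower with palbociclib than with GSK3326595, although replication genes were lower as well. A trend with GC content and gene length was not the whole cause: the list's median was -0.45 (interval -0.696 to -0.311) before and -0.469 (interval -0.633 to -0.34) after their trend was removed. In camera with the preset correlation no single library carried the difference: the largest camera BH-adjusted p over the 6 omissions was 0.000334, without GSK3326595 replicate 2, with a median of -0.305. With an estimated correlation the list was not called on all 6 libraries (camera BH-adjusted p = 0.389). A candidate explanation that stays open is a stronger p53 response to the PRMT5 inhibitor at these doses, which was not tested.

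For the rise of MHC class II genes with palbociclib, GC content and gene length left the median at 2.442 (interval 1.478 to 2.948). That median includes HLA-DQB1, HLA-DQA2 and HLA-DOA, which passed the low-count filter only through the palbociclib libraries. It was not computed without them, so its size is partly tied to the filter. Blood-lineage cells in the palbociclib libraries would bring other abundant transcripts, but of 14 blood markers the 11 under 1 CPM in DMSO reached at most 0.356 CPM (CD14) with palbociclib, against a gain of 66.9 CPM in HLA-DRA; LYZ, which was already present in DMSO, rose from 4.58 to 13.8 CPM. Reads shared between HLA genes would not raise CIITA and CD74, which are not HLA genes, and the smaller of their rises was 1.54 on the log2 scale. For the HLA members themselves, how much of the rise is shared reads stays open. Over the 15 alternative fits between 10 and 11 genes of the group were called higher. The group kept the members admitted through the palbociclib libraries, except that a filter at 1 CPM left out HLA-DQB1. A response of the melanoma cells themselves may account for the rise and stays open as a hypothesis found on these data.

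The fold changes of both inhibitors against DMSO moved together, and both use the same control libraries. When each inhibitor library was set against its own DMSO library, the covariances over the 4 assignments were between 0.0998 and 0.1561, so the lowest lay above 0 by more than their range. The covariance therefore does not come from a DMSO library used in both comparisons alone. The labels do not say whether the DMSO libraries are separate cultures, so a deviation that both share could remain in all 4 assignments. The assignments reuse the same 6 libraries, so their range is not a sampling error. A response common to both inhibitors stays open. Division rate was not measured, and whether any part of such a response follows from slower division was not tested.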
